A study of Rattus norvegicus with 20 samples.

How the data were processed

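Whole blood of 20 Wistar rats was profiled on 1-colour (Cy3) Agilent rat arrays, 1 array per rat, with 4 rats in each of 5 groups, per the labels. The groups were sham operation, untreated esophagitis, STW5 at 0.5 and at 2 ml/kg and omeprazole at 30 mg/kg, given for 7 days before the operation and 10 days after it. The deposited scanner files hold spot intensities from Agilent Feature Extraction 10.7.3.1: per the file headers, the processed intensity was background-subtracted and spatially detrended, low values were replaced by a surrogate, and arrays were not normalized to each other. The authors' deposited value table holds a ratio for each spot, the processed signal divided by the array's median over non-control spots, as found by setting each column against the scanner files, since the labels do not state its scaling. Of its columns 12 follow the scanner file of their own array and 8, those of STW5, follow that of the array of the other dose with the same replicate number. The titles and the design text also number the dose groups in opposite order. Which assignment is right could not be settled, and the titles of the arrays were followed.

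Each array held 62976 spots, 58717 of them non-control, for 30367 probes, and spots of 1 probe were averaged after spots marked as outliers had been left out. No spot was saturated. Of the probes 18005 were named through the reference table of gene symbols, and the name in the scanner file was kept otherwise. The level of a probe was log2 of its processed intensity minus log2 of the array's 75th percentile (71.3 to 308). Probes well above background on at least 4 arrays were tested (17236 probes), and each gene was represented by its brightest probe, which left 15260 genes, 10781 of them with a symbol.

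A linear model with 5 group means was fitted to all 20 arrays with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 15 residual degrees of freedom, prior degrees of freedom 4.22), and data.table (version 1.17.8) for reading. The 7 comparisons were untreated against sham, omeprazole, each STW5 dose and the mean of both doses against untreated, 2 against 0.5 ml/kg, and omeprazole against the mean of both STW5 doses. All tests were two-sided, p values were adjusted by Benjamini-Hochberg over the genes, and a gene passed at an adjusted p below 0.05. Adjusted p values of genes and gene lists in the text come from limma, except those for the relation of lists with signal, which come from permutation. A gene not well above background on any array of a group has only a bound there. Its fold is given as "at least", from the mean of the brighter group over the mean, in the dimmer group, of the higher of the probe's own signal and the lowest signal among probes well above background. No fold is given where this bound is under 1.

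A total of 27 gene lists, with 824 symbols of which 684 were tested, was tested with limma's camera at a preset correlation of 0.01, which compares a list with all other genes. The lists were mature neutrophils, neutrophil granule and precursor genes, monocytes, T cells, B cells, NK and cytotoxic cells, erythroid cells and reticulocytes, platelets and megakaryocytes, eosinophils with basophils and mast cells, dendritic cells and MHC class II, and plasma cells (11 cell type lists). The others were interferon-stimulated genes, inflammatory cytokines and NF-kB targets, immediate early genes, glucocorticoid-induced genes, eicosanoid synthesis and receptors, leukocyte adhesion and chemokine receptors, NRF2 and oxidative stress defence, iron uptake, storage and export, glycolysis and hypoxia, oxidative phosphorylation, fatty acid oxidation and PPAR targets, cell cycle, cytosolic ribosomal proteins, AhR and drug-metabolism genes, T helper and regulatory T cell genes, and proteasome and unfolded protein response. The lists came from general knowledge and not from these arrays. Camera with an estimated correlation and fry, a test of a list without reference to other genes, were alternatives. A list score of an array is the mean over the list's genes of level minus the gene's mean over all arrays. For the relation with signal, the array's median over all genes of the same quantity was subtracted from it, and p values were adjusted over the 27 lists.

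The comparisons, the lists, the tests, the rule for named genes and most alternatives were chosen before the data were examined. By that rule, genes with a symbol were named that passed the threshold and whose groups did not overlap: the 8 with the largest fold in each direction for untreated against sham and for omeprazole and STW5 2 ml/kg against untreated, and the 3 with the largest fold for the other comparisons. Where fewer than 3 qualified, the 3 with the smallest p in each direction were named, and from each list that passed, the 3 members with the smallest p. This gave 217 named results of 167 genes, 24 of them past the threshold. Some list members chosen by this rule are not reported here, though they count in these totals.

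Alternatives were quantile normalization, scaling by the array median or by the 7 spike-in probes, normexp background correction with an offset of 50, the deposited value table, no filter on background, a filter of 10 arrays above background, only the arrays of the groups compared, eBayes with trend and robust, array weights, the replicate number as a block, the mean over a gene's probes, every probe on its own, the erythroid or neutrophil list score as a covariate, the STW5 groups exchanged, and leaving out each array in turn. Array weights were fitted gene by gene, chosen after the default algorithm had not converged. The signal level as a covariate, probes without an imperfect match, and leaving out untreated array 2 with STW5 2 ml/kg arrays 1 and 2 were added after the data had been seen, as were the relation of the lists with signal, the list and named-gene values without each array and the nearest array of each. An imperfect match is an alignment by BLAST+ 2.17.0 of at least 30 bases at 80% identity or more, short of a perfect match, to a probe of another gene that is brighter by at least 1 log2. Slide was not fitted as a block, since each group lay on 1 of the 3 slides and scan followed slide. Correlations between arrays used 1e+05 permutations.

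No array was left out of the comparisons. Control spots and probes well above background on fewer than 4 arrays were left out of the tests, and genes without a symbol were counted but not named.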

Results

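Gene expression was measured in whole blood of 20 Wistar rats, 4 in each of 5 groups, with 1 Agilent array per rat. Reflux esophagitis, inflammation of the esophagus by reflux from the stomach, had been induced by surgery in all groups but sham. Of the operated groups 1 stayed untreated. The others received omeprazole, a proton pump inhibitor lowering gastric acid, at 30 mg/kg, or STW5, a liquid of medicinal plant extracts, at 0.5 or 2 ml/kg. The 75th percentile of an array's signal ranged from 71.3 to 308 with a median of 164, and 43.1% to 57.4% of the probes were well above background. The median standard error of a log2 change between 2 groups of 4 was 0.35 over the 15260 genes tested. Across genes, which are not independent replicates, arrays of the sham group correlated with each other at 0.975 to 0.986 and those of the untreated group at 0.877 to 0.949.

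The sham and untreated arrays lay on slide 1, all STW5 arrays on slide 2 and the omeprazole arrays on slide 3. Slide and treatment therefore cannot be told apart in any comparison of treated with untreated rats, or of omeprazole with STW5. The labels of the STW5 doses also conflict, the titles were followed, and which arrays belong to which dose stays unsettled. Gene changes below are log2 changes ± standard error with 4 arrays per group unless stated otherwise. Folds given as at least allow for background but not for sampling error. They hold for the scanner files' background subtraction: with normexp, whose offset shrinks changes, all 21 lay below their bound. The median of a gene list is relative to that of all genes in the comparison, but members are counted as higher or lower than 0. By such counts most genes fall on the side of the median of all genes.

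Gene levels moved with the signal level of the arrays, within groups as well as over all arrays. Every level has the array's 75th percentile subtracted, and the median of all genes correlated with log2 of that percentile at Pearson r = -0.912 over 20 arrays, a relation that the subtraction partly builds in. The scores of all 27 lists were therefore taken relative to the median of all genes of the array. Of the 27, 11 correlated with log2 of the 75th percentile at an adjusted p below 0.05, 8 higher and 3 lower with more signal, and within groups 5 did. Leukocyte adhesion and chemokine receptor genes gave Pearson r = 0.866 (permutation p = 1e-05, adjusted 0.00027) and Spearman rho = 0.815 (permutation p = 4e-05, adjusted 0.00108), where 1e-05 is the smallest p the permutations can give. Their r was 0.861 within groups and 0.854 without the 2 arrays of most extreme signal. Erythroid genes gave Pearson r = -0.732 (permutation p = 0.0002, adjusted 0.00113) and Spearman rho = -0.752 (permutation p = 0.00018, adjusted 0.00122). Their r was -0.823 within groups and -0.672 without the 2 extreme arrays.

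Untreated esophagitis was compared with sham operation to see how the blood differed after reflux. Relative to all other genes, mature neutrophil transcripts were higher in the untreated rats. Erythroid transcripts were lower, with scores below sham (0.26 to 0.90) only on untreated arrays 3 and 4 (-1.57, -1.33), the brightest of slide 1. T-cell and B-cell transcripts were lower too, resting on untreated array 2. All 4 calls were made with a preset correlation and none held with an estimated one (adjusted p = 0.258 to 0.606). All 20 tested neutrophil genes were higher, with a median 1.17 above that of all genes. They included Ncf1, a subunit of the phagocyte oxidase, at 1.30 ± 0.34, the myeloid integrin gene Itgam at 1.57 ± 0.48 and the chemokine receptor gene Cxcr2 at 1.35 ± 0.45. Of the 22 T-cell genes 21 were lower, with a relative median of -0.68, among them the homing receptor gene Ccr7 at -1.75 ± 0.49, Cd3g of the T-cell receptor complex at -1.58 ± 0.46 and the receptor kinase gene Lck at -1.56 ± 0.50. All 19 B-cell genes were lower, with a median of -0.58: Cd72 lay at -1.82 ± 0.58, the kinase gene Blk at -1.56 ± 0.58 and Ms4a1, which encodes a B-cell surface antigen, at -1.25 ± 0.57. The erythroid list, with 40 of 43 members lower and a median of -0.95, held the transcription factor gene Klf1 at -1.45 ± 0.47, the red-cell membrane gene Epb42 at -1.59 ± 0.56 and Trim58 at -1.56 ± 0.56. Without untreated array 2 calls ended for T cells (median -0.13, adjusted p = 0.318) and B cells (-0.0074, 0.657). The neutrophil median was then 0.74, with the call kept. Changes then shrank by over 1.5 times for Blk (-0.90), Cd3g (-1.02), Cd72 (-1.19), Itgam (1.01), Lck (-0.83) and Ms4a1 (-0.46).

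Several further lists were called higher in untreated than in sham rats, and none of these calls held with an estimated correlation (adjusted p = 0.258 to 0.54). Of the platelet and megakaryocyte genes 15 of 21 were higher (relative median 0.72), with the adhesion receptor gene Selp at 2.67 ± 0.76, Ltbp1 at 1.42 ± 0.51 and Thbs1 at least 2.15-fold higher. Monocyte genes were higher for 12 of 18 members (median 0.74), with Vcan at 2.06 ± 0.50 and Lgals3 at 1.26 ± 0.45, but Cd300e lay at -1.10 ± 0.40. In the plasma cell list, 6 of 8 genes were higher (median 0.83), with Sdc1 at 2.47 ± 0.73 and Xbp1, a transcription factor of the unfolded protein response, at 0.76 ± 0.32. No fold is given for Prdm1, which was well above background on 2 untreated arrays and on 0 sham arrays. Inflammatory cytokines and NF-kB targets were higher for 20 of 24 members (median 0.89), including Socs3, a feedback inhibitor of cytokine signalling, at 1.17 ± 0.32, the cytokine gene Tnf at 1.40 ± 0.46 and Tnfaip2 at least 3.96-fold higher. Immediate early genes were higher for 19 of 23 members (median 0.54), with Jun at 2.28 ± 0.48, Gadd45b at 1.02 ± 0.28 and Junb at 1.08 ± 0.34. Glucocorticoid-induced genes were higher for 15 of 19 (median 0.89), with Cebpd at 1.27 ± 0.44, the receptor co-chaperone gene Fkbp5 at 1.18 ± 0.42 and Sgk1 at 0.97 ± 0.36. Without untreated array 2 the glucocorticoid call was lost (median 0.31, adjusted p = 0.118). Changes were then over 1.5 times smaller for Fkbp5 (0.72), Lgals3 (0.81) and Tnf (0.91).

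Metabolic and receptor lists were also called between untreated and sham rats, again with none held by an estimated correlation (adjusted p = 0.258 to 0.61). Of the glycolysis and hypoxia genes 26 of 31 were higher, with a relative median of 0.76: the hexokinase genes Hk3 and Hk2 lay at 2.88 ± 0.80 and at least 1.62-fold higher, and the glucose transporter gene Slc2a1 at 0.90 ± 0.29. Of the eicosanoid genes 13 of 22 were higher, with a median of 0.52, led by the leukotriene synthesis genes Alox5 at 1.61 ± 0.47 and Alox5ap at 1.31 ± 0.47 and by Pla2g7 at 1.24 ± 0.42. Of the leukocyte adhesion and chemokine receptor genes 19 of 31 were higher and 12 lower, with a median of 0.26. Of the fatty acid oxidation genes 17 of 24 were higher, with a median of 0.48. Cpt2 lay at 0.73 ± 0.27 and Acaa1a at 0.71 ± 0.28, whereas the carnitine carrier gene Slc25a20 lay at -1.45 ± 0.55. Of the oxidative phosphorylation genes 41 of 57 were lower, with a median of -0.21, a direction that normexp background correction turned to 0.0038. They included the ATP synthase genes Atp5f1c at -0.62 ± 0.24 and Atp5f1b at -1.56 ± 0.61, and Cox6a1 at -0.95 ± 0.40. Of the cytosolic ribosomal protein genes 72 of 78 were lower, with a median of -0.17, a direction that quantile normalization turned to 0.09 and normexp to 0.06. Rpl5 lay at -1.001 ± 0.37, Rps23 at -0.63 ± 0.26 and Rps6 at -0.62 ± 0.30. No call was left without untreated array 2 for eicosanoid genes (median 0.35, adjusted p = 0.148) and fatty acid oxidation (0.30, 0.352). Nor was that of adhesion genes without sham array 1 or untreated array 3 or 4 (0.03 to 0.30, 0.0567 to 0.235). Calls ended for oxidative phosphorylation without sham array 1 or 2 or untreated array 1 or 3 (-0.20 to -0.02, 0.1 to 0.628) and ribosomal proteins without untreated array 3 (0.03, 0.235). Log2 changes were over 1.5 times smaller without untreated array 2 for Alox5ap (0.85), without untreated array 3 for Atp5f1b (-0.94), Atp5f1c (-0.38), Rpl5 (-0.55), Rps6 (-0.31) and Slc25a20 (-0.93) and without untreated array 4 for Hk3 (1.80).

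By limma, 1 of 15260 genes passed in untreated against sham rats: Timmdc1, an assembly factor of mitochondrial complex I, fell by 1.51 ± 0.23 on the log2 scale (adjusted p = 0.0434), with all 4 untreated arrays below all 4 sham arrays. The other genes with the smallest p did not pass: Clock, a circadian transcription factor gene, was at least 1.61-fold higher, N4bp1 lay at 1.53 ± 0.31, Slc38a7 at 1.67 ± 0.35, Pla2g2f at -1.47 ± 0.33, and Cimap2 was at least 3.42-fold lower, each with an adjusted p of 0.242. Of the 27 gene lists, 16 passed limma's camera test with a preset correlation, 11 higher and 5 lower, at adjusted p = 5.61e-08 to 0.0434 over the lists. Fry called 0 lists here and in every other comparison. Adjusted over the list alone, 3 neutrophil, 1 monocyte, 3 T-cell, 1 platelet, 1 plasma cell, 1 inflammatory, 3 immediate early and 10 glycolysis genes passed, and 0 in the other 8 lists. Over all genes tested, 0 members of any list passed. The median of all genes was -0.19 in this comparison, and 0.37 with spike-in scaling. Spots were well above background on part of the arrays for Clock (3 untreated, 0 sham), Slc38a7 (2 sham), Timmdc1 (2 untreated, 3 sham), Pla2g2f (3 untreated), Cimap2 (0 untreated, 2 sham), Cd300e (1 untreated, 3 sham), Cd72 (2 untreated) and Blk (3 untreated). The same held for Ms4a1 (3 untreated), Ltbp1 (1 sham), Thbs1 (3 untreated, 0 sham), Sdc1 (3 sham), Tnfaip2 (3 untreated, 0 sham), Hk3 (2 sham) and Hk2 (3 untreated, 0 sham). With normexp, Clock and Hk2 turned to -0.14 and -0.05.

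The call of Timmdc1 ended without sham array 1, 2 or 3 or untreated array 2, 3 or 4 (adjusted p = 0.0720 to 0.196) and under 11 other alternatives (adjusted p = 0.0632 to 0.424), and 1762 genes passed without untreated array 1. Fitted on the 8 arrays compared alone, 0 genes and 17 lists passed. With the neutrophil list score as a covariate 5 lists passed, 4 of them among the 16. Untreated array 1 was nearest to sham array 3 (r = 0.992), with a mean r of 0.984 to sham and 0.92 to the other untreated arrays, which leaves open whether its label is right or that rat had no esophagitis. Untreated array 2 stood apart, with 15 of 27 list scores outside the range of the other 19 arrays: 1.68 for iron uptake, storage and export (others at most 0.44), 1.52 for neutrophils (at most 0.99), -2.53 for T cells and -2.16 for B cells (at least -0.77 and -0.69). Without it 12 lists passed, 11 of them among the 16.

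**Figure D1:**
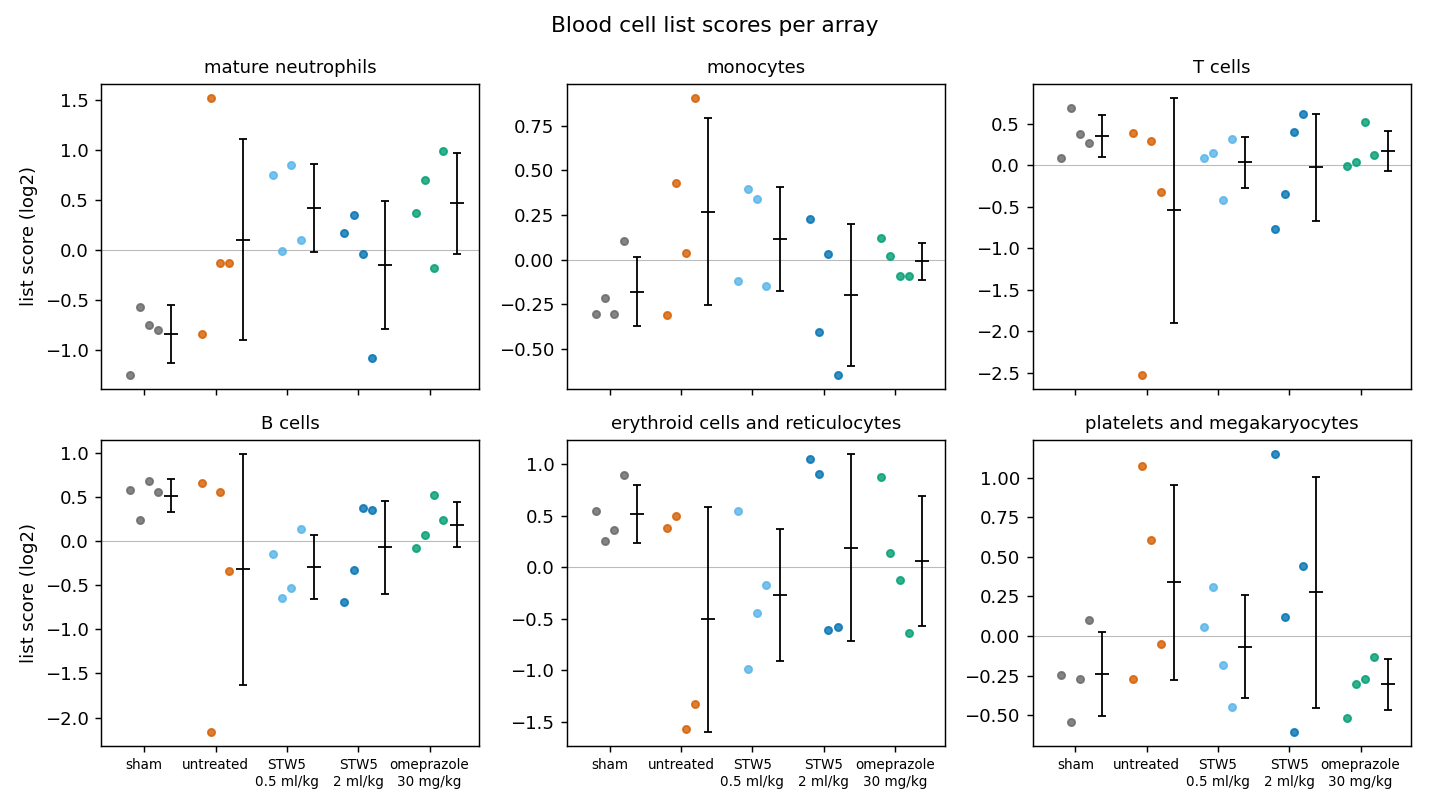
List scores (log2, mean over a list's genes of level minus the gene's mean over all arrays) of 6 blood cell lists on each array, one panel per list, with dots for arrays in 5 groups and a bar for mean ± SD (n = 4). The neutrophil score averaged -0.84 ± 0.29 in sham and 0.10 ± 1.00 in untreated rats.

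Omeprazole was compared with no treatment in operated rats to see what the drug changed in blood. By limma, 637 genes differed, 53 of them higher and 584 lower with omeprazole, and 155 of the 637 had a gene symbol. The 8 named genes that fell most were Hist1h2bq, a histone gene, at -5.03 ± 0.45 (adjusted p = 3.49e-07), Txnip, which encodes an inhibitor of thioredoxin and of glucose uptake, at -4.41 ± 0.43 (adjusted p = 1.02e-06), the rat MHC class I gene RT1-T24-4 at -3.65 ± 0.38, the chemokine gene Cxcl16 at -3.53 ± 0.90, and the trypsin gene Try10 at -3.52 ± 0.83. With them stood another trypsin gene, Prss3, at least 11.8-fold lower, Nudt9, an ADP-ribose hydrolase gene, at least 6.37-fold lower, and the helicase gene Helz at least 5.97-fold lower. Among the 53 that rose, Clec5a, a C-type lectin receptor gene of myeloid cells, was at least 4.24-fold higher (adjusted p = 0.000117) and Mapk8ip3, a scaffold of kinase signalling, at least 3.29-fold higher. The ADP-ribosyltransferase gene Art2b lay at 1.85 ± 0.50, Mybph at 1.45 ± 0.35, the natural killer receptor gene Klra17 at 1.45 ± 0.40, Cfap141 at 1.43 ± 0.38, the immunoglobulin-like receptor gene Lilrc2 at 1.42 ± 0.37 and the lectin receptor gene Clec4a2 at 1.37 ± 0.35. Each of these 16 genes had all 4 omeprazole arrays on one side of all 4 untreated arrays, at adjusted p = 3.49e-07 to 0.0484.

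**Figure D2:**
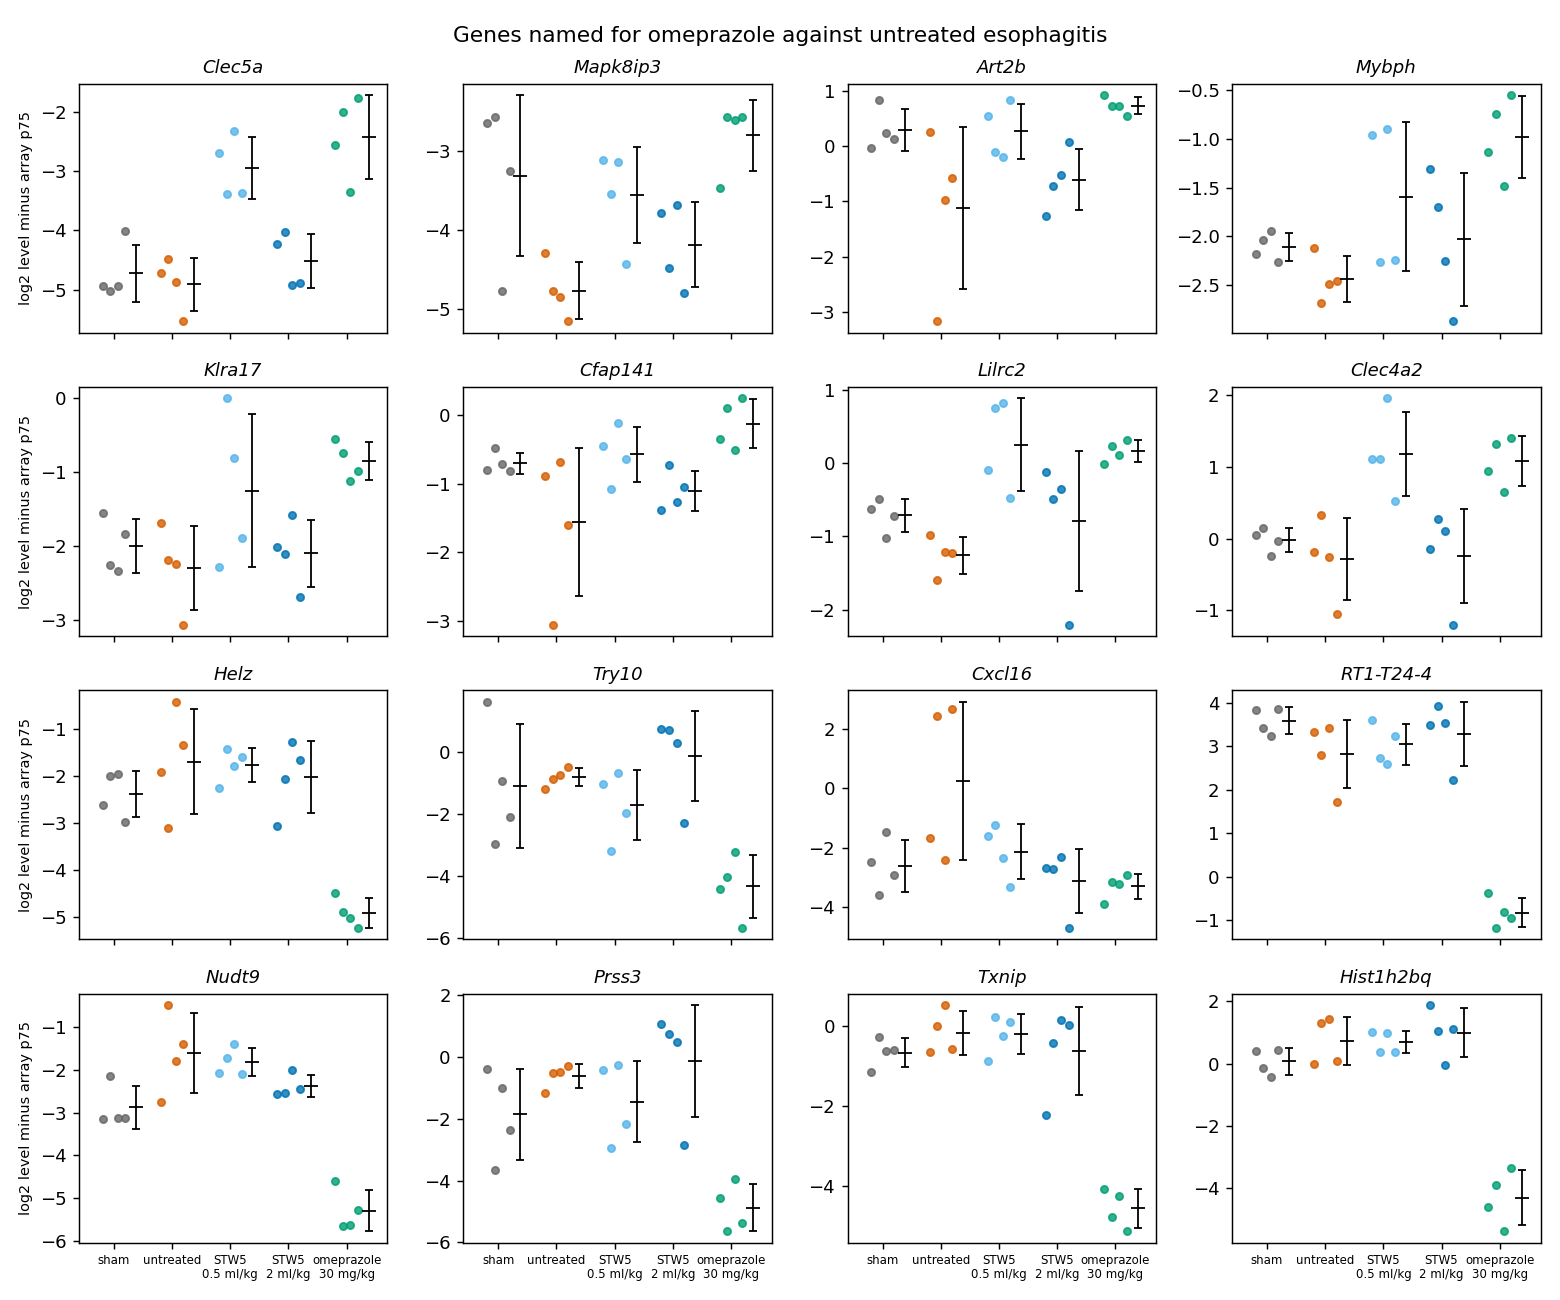
Level of the 16 genes named for omeprazole against untreated rats (log2 signal minus the array's 75th percentile), one panel per gene, with dots for arrays in 5 groups and a bar for mean ± SD (n = 4). All omeprazole arrays lie beyond all untreated arrays in each panel.

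Relative to all genes, erythroid transcripts were called higher with omeprazole and platelet transcripts lower. T-cell transcripts were called higher too, which rested on untreated array 2, and none of the 3 calls held with an estimated correlation (adjusted p = 0.967 for each). T-cell genes were higher for 19 of 22 members (relative median 0.68), with Ccr7 at 1.64 ± 0.49, Cd3g at 1.39 ± 0.46 and Cd2 at 1.18 ± 0.51. Erythroid genes were higher for 39 of 43 (median 0.52), with the spectrin gene Sptb at 1.5 ± 0.67. Against that list's direction Cpox, an enzyme of heme synthesis, was at least 2.37-fold lower (adjusted p = 0.0105). Of the platelet genes 18 of 21 were lower (median -0.58). Selp lay at -2.60 ± 0.76, Ltbp1 at -1.70 ± 0.51 and Vwf at -0.82 ± 0.34. These 3 lists passed camera with a preset correlation at adjusted p = 0.00969 to 0.0112. Calls ended for T cells without untreated array 2 (median 0.0021, adjusted p = 0.722), erythroid cells without omeprazole array 1 or untreated array 3 or 4 (0.25 to 0.34, 0.215 to 0.413) and platelets without omeprazole array 1 or untreated array 2 or 3 (-0.54 to -0.22, 0.0629 to 0.173). Adjusted over the list alone, 0 T-cell genes, 1 erythroid gene (Cpox) and 2 platelet genes passed, against 0, 1 and 0 over all genes tested. The median of all genes was 0.10, and 0.18 with spike-in scaling. Spots were above background on part of the arrays for Clec5a (3 omeprazole, 0 untreated), Mapk8ip3 (3 omeprazole, 0 untreated), Txnip (1 omeprazole), Prss3 (0 omeprazole), Nudt9 (0 omeprazole), Cxcl16 (3 omeprazole), Helz (0 omeprazole), Cd2 (3 untreated), Cpox (0 omeprazole, 2 untreated) and Ltbp1 (2 omeprazole). Changes shrank by over 1.5 times without untreated array 2 for Cd2 (0.42) and Cd3g (0.83) and without untreated array 3 for Sptb (0.69).

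Probes lower on the omeprazole arrays often imperfectly matched a brighter probe of another gene. Of 890 tested probes with such a match 295 (33.1%) were called lower, against 329 (2.01%) of 16346 without, and 259 genes (17 higher, 242 lower) passed when only probes without a match were tested. None of the 16 named genes had such a match, but transcripts were not searched. Further probes of the same genes, present for 30 of the 637, had a median change of -0.02 where the called probes had -1.33. Those of Hist1h2bq, Try10 and Art2b stood at -0.68, -0.48 and 2.22.

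Of the 16 named calls, that of Klra17 ended without untreated array 2, 3 or 4 or any omeprazole array (adjusted p = 0.0715 to 0.196), and that of Art2b without untreated array 2 or 3 or any omeprazole array (0.0537 to 0.0936). The call of Cfap141 ended without untreated array 2 or 4 or omeprazole array 1, 2 or 4 (0.0519 to 0.116), that of Cxcl16 without untreated array 2 or 4 or omeprazole array 1, 2 or 3 (0.0596 to 0.12), and that of Lilrc2 without untreated array 2 or 4 or omeprazole array 2, 3 or 4 (0.0663 to 0.0867). The call of Clec4a2 ended without untreated array 4 or omeprazole array 2 or 4 (0.0894 to 0.117), that of Mybph without untreated array 2 or omeprazole array 2 or 4 (0.0528 to 0.0728), and that of Try10 without omeprazole array 4 (0.0644) or with the mean over its probes (0.176). Without untreated array 2 the log2 changes of Art2b, Cfap141 and Cxcl16 were 1.165, 0.93 and -2.81, and without untreated array 4 that of Cxcl16 was -2.73. Normexp ended the calls of Clec5a (0.66), Mapk8ip3 (0.53), Klra17 (0.78), Prss3 (-1.355), Cxcl16 (-1.98), Try10 (-1.02) and Cpox (-0.21), with these log2 changes, at adjusted p = 0.0720 to 0.660, and moved Hist1h2bq to -2.26, Txnip to -1.56, Nudt9 to -0.955 and Helz to -0.83. Spike-in scaling ended the calls of Mapk8ip3, Art2b, Mybph, Klra17, Cfap141, Lilrc2, Clec4a2 and Cpox (0.0538 to 0.176). With only the 8 arrays compared the calls of Klra17, Art2b, Cfap141, Clec4a2 and Cxcl16 ended (0.0541 to 0.301), and with no filter those of Klra17, Art2b, Cfap141, Lilrc2 and Clec4a2 (0.0522 to 0.0905). Quantile normalization, the median of each array, the deposited value table and the neutrophil covariate ended only that of Klra17 (0.0515 to 0.0535). The count of genes was 1142 without untreated array 1, and 6 lists passed without untreated array 1 or 2.

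**Figure D3:**
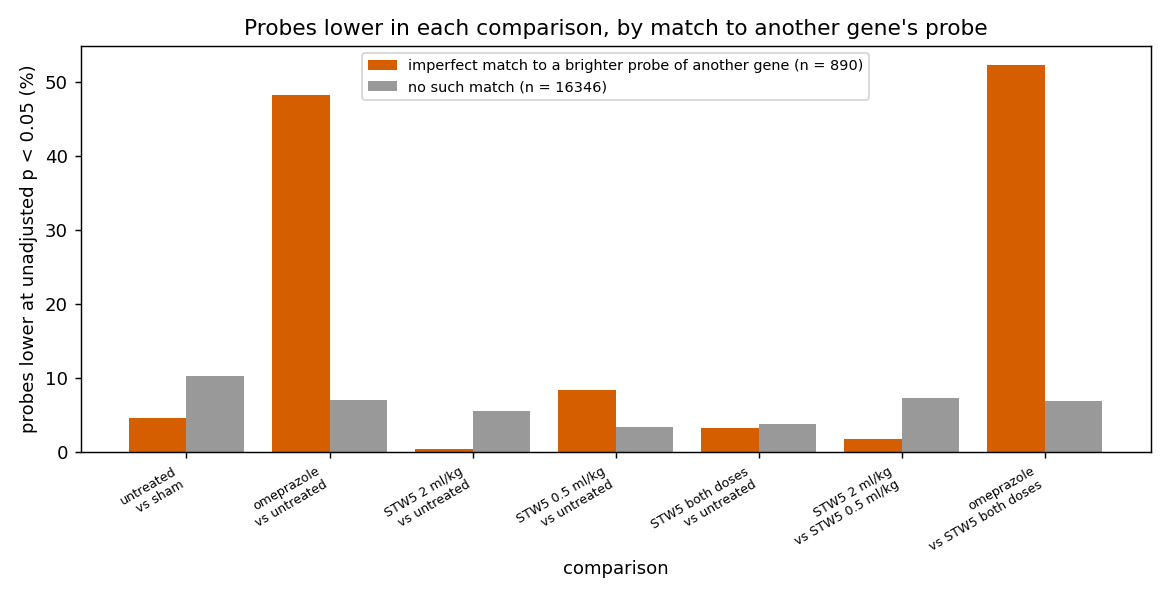
Percentage of probes lower at an unadjusted p below 0.05 in each of 7 comparisons, with one bar for the 890 probes that imperfectly match a brighter probe of another gene and one for the 16346 that do not. For omeprazole against untreated rats the bars stand at 48.2% and 7.05%, and for omeprazole against both STW5 doses at 52.3% and 6.88%.

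STW5 at 2 ml/kg was compared with no treatment to see what the higher dose changed. Relative to all genes, erythroid and ribosomal protein transcripts were called higher in the treated rats and monocyte, dendritic cell and plasma cell transcripts lower. Neutrophil transcripts were called lower too, a direction that turned without untreated array 2 and without STW5 2 ml/kg array 4. None of these calls held with an estimated correlation (adjusted p = 0.577 to 0.82). Erythroid genes were higher for 40 of 43 members (relative median 0.74), with Bpgm, an enzyme of red cells, at 1.06 ± 0.37, the heme synthesis gene Alas2 at 0.96 ± 0.37 and Car2 at 1.02 ± 0.39. All 78 ribosomal protein genes were higher (median 0.42). Rpl37a lay at 0.78 ± 0.26, Rpsa at 0.80 ± 0.27 and Rpl12 at 0.81 ± 0.27. Monocyte genes were lower for 11 of 18 (median -0.75), with Cd68 at -1.40 ± 0.47 and Klf4 at -1.08 ± 0.33, while Cd300e lay at 1.46 ± 0.40. In the list of dendritic cells and MHC class II, 13 of 18 genes were lower (median -0.52), with RT1-DMa at -1.19 ± 0.36 and Batf3 at least 1.42-fold lower, but Zbtb46 at 1.32 ± 0.48. Plasma cell genes were lower for 7 of 8 (median -0.47), with Sdc1 at -2.85 ± 0.73, Xbp1 at -0.81 ± 0.32 and Fkbp11 at -0.53 ± 0.35. Of the neutrophil genes 11 of 20 were lower (median -0.34), with the oxidase genes Cybb at -1.26 ± 0.40 and Ncf1 at -0.91 ± 0.34 and Trem1 at -1.04 ± 0.50. The call was lost for erythroid cells without 2 ml/kg array 1 or 2 or untreated array 3 or 4 (median 0.26 to 0.58, adjusted p = 0.0633 to 0.155), dendritic cells without untreated array 4 (-0.24, 0.102) and plasma cells without untreated array 2 (-0.32, 0.0794). No call was left for neutrophils without 2 ml/kg array 3 or 4 or untreated array 2 (-0.43 to 0.17, 0.0643 to 0.947). The ribosomal protein median was 0.09 without untreated array 3, with the call kept. Over 1.5 times smaller changes came without 2 ml/kg array 4 for Trem1 (-0.64), without untreated array 2 for Fkbp11 (-0.23) and Trem1 (-0.68), without untreated array 3 for Zbtb46 (0.87) and without untreated array 4 for Cd68 (-0.88). That of Fkbp11 was larger without untreated array 3 (-0.82).

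Inflammatory and metabolic lists were called lower as well with 2 ml/kg, and none of these calls held with an estimated correlation (adjusted p = 0.577 for each). Inflammatory genes were lower for 16 of 24 (relative median -0.33), with Icam1 at -1.37 ± 0.41 and Il18 at -2.08 ± 0.74, whereas Osm lay at 1.19 ± 0.36. Glucocorticoid-induced genes were lower for 15 of 19 (median -0.52). Klf9 lay at -1.09 ± 0.36 and Errfi1 at -1.08 ± 0.38, and Cxcr4 at 0.69 ± 0.21. Glycolysis genes were lower for 25 of 31 (median -0.48), with Pgam1 at -0.85 ± 0.26, Bnip3 at least 2.33-fold lower and Pfkfb3 at 0.85 ± 0.34. Fatty acid oxidation genes were lower for 18 of 24 (median -0.54), with Cpt2 at -1.03 ± 0.27, Eci1 at -0.86 ± 0.30 and Etfdh at -0.71 ± 0.30. The proteasome and unfolded protein list had 25 of 40 genes lower (median -0.25). Psmd1 lay at -0.65 ± 0.23 and Psmc1 at -0.69 ± 0.26, and Psmd4 at 0.98 ± 0.39. No call was left for inflammatory genes without 2 ml/kg array 4 or untreated array 2 (median -0.18, adjusted p = 0.12 to 0.175), glucocorticoid-induced genes without untreated array 2 (-0.21, 0.429) and the proteasome list without untreated array 4 (-0.14, 0.0997). Log2 changes were over 1.5 times smaller without 2 ml/kg array 1 for Etfdh (-0.40), without untreated array 2 for Bnip3 (-1.005), Errfi1 (-0.52), Klf9 (-0.67) and Psmc1 (-0.44), without untreated array 3 for Psmd4 (0.63) and without untreated array 4 for Eci1 (-0.55) and Il18 (-1.38).

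By limma 0 genes passed at 2 ml/kg (smallest adjusted p = 0.0687), with 3588 at unadjusted p below 0.05. The named genes with the smallest p were Hif3a, a subunit of hypoxia-inducible factor, at 2.04 ± 0.36, Sytl4 at 1.40 ± 0.27 and Atxn7l2 at 1.27 ± 0.25 on the higher side. On the lower side they were the thrombomodulin gene Thbd at -2.94 ± 0.65, Etv5 at -2.33 ± 0.54 and Slc25a24 at -1.68 ± 0.41, and for all 6 the adjusted p was 0.0973. Camera called 11 lists at adjusted p = 3.16e-06 to 0.0441, 2 higher and 9 lower. Adjusted over the list alone, 1 monocyte gene passed as higher and 4 as lower, 1 inflammatory gene each way, 1 plasma cell gene and 1 fatty acid oxidation gene as lower, and 0 in the other 7 lists, with 0 over all genes tested in every list. The median of all genes was 0.14. Spots were above background on part of the arrays for Thbd (1 STW5, 3 untreated), Etv5 (1 STW5), Cd300e (1 untreated), Batf3 (0 STW5, 3 untreated), Sdc1 (1 STW5), Fkbp11 (1 STW5, 3 untreated), Il18 (3 STW5) and Errfi1 (2 STW5). The same held for Bnip3 (0 STW5, 3 untreated), Cpt2 (2 STW5) and Etfdh (1 STW5). With spike-in scaling, which put the median of all genes at -0.87, 3672 genes passed, 7 higher and 3665 lower, and Alas2, Cxcr4, Pfkfb3, Rpl37a, Rpsa, Rpl12 and Psmd4 turned to values below 0. Normexp turned Batf3, Fkbp11, Bnip3 and Etfdh to values above 0. The count was 3012 without untreated array 1, 1 without untreated array 4 and 1036 without STW5 2 ml/kg array 3, and 17 lists passed without STW5 2 ml/kg array 1. With the arrays' signal level as a covariate 10 lists passed, 2 of them among the 11. With the doses exchanged, as the deposited value table has them, 4 lists passed in place of 11, and in that table Trem1, Klf4, Alas2, Xbp1, Bnip3, Etfdh and Rpl37a had the opposite sign.

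STW5 at 0.5 ml/kg was set against no treatment in the same way. Relative to all genes, transcripts of neutrophil granules and of eosinophils, basophils and mast cells were called higher and platelet transcripts lower. T-cell transcripts were called higher too, a direction that turned without untreated array 2, and none of the 4 calls held with an estimated correlation (adjusted p = 0.105 to 0.974). T-cell genes were higher for 21 of 22 members (relative median 0.57), with Cd3g at 1.14 ± 0.46, Cd2 at 1.18 ± 0.51 and Ccr7 at 1.11 ± 0.49. Of the granule and precursor genes 12 of 13 were higher (median 0.59), with the defensin gene Defa7 at 0.77 ± 0.31, Retnlg at 1.34 ± 0.56 and Camp at 1.39 ± 0.69. Eosinophil, basophil and mast cell genes were higher for 9 of 12 (median 0.43), with the protease genes Mcpt8l2 at least 3.32-fold higher and Mcpt8 at 1.59 ± 0.67, and Rnase2 at 1.51 ± 0.40. Platelet genes were lower for 15 of 21 (median -0.21), with Selp at -1.80 ± 0.76, Sparc at -2.20 ± 1.03 and Ltbp1 at -1.07 ± 0.51. Camera called these 4 lists at adjusted p = 9.91e-05 to 0.0275. Adjusted over the list alone, 2 eosinophil, basophil and mast cell genes passed and 0 in the other 3 lists, with 0 over all genes tested. Calls ended for T cells without untreated array 2 (median -0.15, adjusted p = 0.723), neutrophil granules without 0.5 ml/kg array 2 or untreated array 3 (0.35 to 0.44, 0.0808 to 0.216) and eosinophils without untreated array 3 (0.45, 0.125). The call was lost for platelets without 0.5 ml/kg array 4 or untreated array 2 or 3 (-0.10 to -0.0068, 0.45 to 0.662). Changes shrank by over 1.5 times without 0.5 ml/kg array 1 for Retnlg (0.81), without 0.5 ml/kg array 2 for Defa7 (0.47), without untreated array 2 for Ccr7 (0.73), Cd2 (0.41), Cd3g (0.58) and Sparc (-0.65), without untreated array 3 for Camp (0.91) and without untreated array 4 for Ltbp1 (-0.71) and Selp (-0.96). Larger ones came for Ccr7 without untreated array 1 (1.79) and Camp without untreated array 2 (2.14).

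By limma 0 genes passed at 0.5 ml/kg (smallest adjusted p = 0.181), with 906 at unadjusted p below 0.05. The smallest p values belonged to Clec5a at least 2.96-fold higher, Klra2 at 1.97 ± 0.42 and Mogat2 at 1.63 ± 0.38. On the lower side they belonged to Cyp2t1 at least 2.88-fold lower, Lrrc8a at -1.67 ± 0.38 and Rcor3 at -1.26 ± 0.30, at adjusted p = 0.181 to 0.449. All genes had a median of 0.02, and of 0.27 with spike-in scaling. Spots were above background on part of the arrays for Clec5a (0 untreated), Mogat2 (3 untreated), Cyp2t1 (0 STW5, 3 untreated), Lrrc8a (1 STW5, 3 untreated), Rcor3 (2 STW5, 3 untreated), Cd2 (3 untreated), Sparc (3 untreated) and Mcpt8l2 (0 untreated). Without untreated array 1 or 3, 5 genes passed in each case, and the count of lists was 8, 11 and 7 without untreated array 1, 2 and 4 and 7 without STW5 0.5 ml/kg array 3. With the doses exchanged 11 lists passed in place of 4, and in the deposited value table Camp, Mcpt8l2 and Mcpt8 lay at -0.18, -0.06 and -0.04.

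The mean of both STW5 doses does not depend on which dose is which. With 8 STW5 against 4 untreated arrays, erythroid, ribosomal protein and T-cell transcripts were called higher relative to all genes, and 6 lists lower. The direction of the T-cell and glucocorticoid lists turned without untreated array 2, that of ribosomal proteins without untreated array 3, and none of the 9 calls held with an estimated correlation (adjusted p = 0.56 to 0.77). T-cell genes were higher for 21 of 22 (relative median 0.49), with Cd3g at 0.94 ± 0.40, Ccr7 at 0.79 ± 0.43 and Cd3d at 0.62 ± 0.35. Erythroid genes were higher for 39 of 43 (median 0.43). Bpgm lay at 0.56 ± 0.32, Mkrn1 at 0.70 ± 0.42 and Tmod1 at 0.70 ± 0.43. Ribosomal protein genes were higher for 76 of 78 (median 0.17), with Rpl15 at 0.65 ± 0.31, Rps23 at 0.38 ± 0.22 and Rps10 at 0.36 ± 0.21. Monocyte genes were lower for 12 of 18 (median -0.53), with Cd68 at -0.98 ± 0.40 and Cd14 at -1.36 ± 0.57, but Cd300e at 1.12 ± 0.34. In the dendritic cell list 13 of 18 genes were lower (median -0.54), with Batf3 at -0.998 ± 0.31, Flt3 at -0.79 ± 0.30 and RT1-DMa at -0.79 ± 0.31. Glycolysis genes were lower for 25 of 31 (median -0.42). Pgam1 lay at -0.56 ± 0.23, Hif1a at -0.67 ± 0.29 and Gpi at -0.45 ± 0.20. Fatty acid oxidation genes were lower for 19 of 24 (median -0.32), with Cpt2 at -0.67 ± 0.24, Etfb at -0.43 ± 0.18 and Acads at -0.49 ± 0.22, whose probe imperfectly matches a brighter one. Glucocorticoid-induced genes were lower for 12 of 19 (median -0.23), with Klf9 at -1.01 ± 0.31, Errfi1 at -0.95 ± 0.33 and Zbtb16 at -1.02 ± 0.39. The proteasome list had 22 of 40 genes lower (median -0.13), with Psmd1 at -0.56 ± 0.20, Psmc1 at -0.51 ± 0.22 and Canx at -0.40 ± 0.20. The call was lost for T cells without 2 ml/kg array 4 or untreated array 2 (median -0.23 to 0.34, adjusted p = 0.0507 to 0.193), erythroid cells without 2 ml/kg array 1 or untreated array 3 or 4 (0.06 to 0.27, 0.0523 to 0.579) and ribosomal proteins without untreated array 3 (-0.04, 0.88). No call was left for monocytes without 2 ml/kg array 4 or untreated array 2 or 4 (-0.53 to -0.18, 0.0507 to 0.272), dendritic cells without untreated array 4 (-0.18, 0.159) and glycolysis without untreated array 2 (-0.17, 0.191). Calls ended for fatty acid oxidation without untreated array 2 (-0.17, 0.203), glucocorticoid-induced genes without 0.5 ml/kg array 4 or 2 ml/kg array 1 or 4 or untreated array 2 or 3 (-0.25 to 0.0022, 0.0507 to 0.918) and the proteasome list without 0.5 ml/kg array 4 or 2 ml/kg array 4 or untreated array 2 or 4 (-0.17 to -0.0098, 0.0507 to 0.824). Over 1.5 times smaller changes came without untreated array 2 for Ccr7 (0.40), Cd14 (-0.55), Cd3d (0.09), Cd3g (0.38), Errfi1 (-0.39), Etfb (-0.25), Klf9 (-0.59), Psmc1 (-0.27), Rpl15 (0.19) and Zbtb16 (-0.53), without untreated array 3 for Bpgm (0.30), Mkrn1 (0.22), Rps10 (0.15), Rps23 (0.23) and Tmod1 (0.26) and without untreated array 4 for Ccr7 (0.52), Cd68 (-0.47), Pgam1 (-0.36) and RT1-DMa (-0.49). Larger by as much were those of Ccr7 (1.46), Cd14 (-2.07), Mkrn1 (1.15) and Rps23 (0.61) without untreated array 1 and of Tmod1 (1.14) without untreated array 2.

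For both doses together limma called 0 genes (smallest adjusted p = 0.273), with 1455 at unadjusted p below 0.05. The smallest p values belonged to Hif3a at 1.49 ± 0.31, Sfr1 at least 1.88-fold higher and Armcx6 at 1.28 ± 0.31. On the lower side they belonged to Cyp2t1 at least 2.2-fold lower, Ggcx at -0.92 ± 0.22 and Pank3 at -1.33 ± 0.32, at adjusted p = 0.364 to 0.46. Camera called 9 lists at adjusted p = 0.00038 to 0.0275, 3 higher and 6 lower. In each of the 9 lists 0 members passed adjusted over the list alone, and 0 over all genes tested. All genes had a median of 0.10, and of -0.29 with spike-in scaling. Spots were above background on part of the arrays for Sfr1 (3 STW5, 0 untreated), Cyp2t1 (0 STW5, 3 untreated), Pank3 (1 STW5, 3 untreated), Cd300e (1 untreated), Batf3 (2 STW5, 3 untreated), Flt3 (7 STW5, 3 untreated), Errfi1 (6 STW5) and Zbtb16 (1 STW5, 3 untreated). The same held for Hif1a (2 STW5, 3 untreated), Cpt2 (6 STW5), Rpl15 (3 untreated) and Canx (7 STW5). With spike-in scaling Rps10 turned to -0.02, and with normexp Hif1a turned to 0.04. The count of genes was 161 without untreated array 1 and 1 without untreated array 3, and 14 lists passed without untreated array 1.

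STW5 2 ml/kg was compared with 0.5 ml/kg on slide 2, with signs that turn if the doses are exchanged. Relative to all genes, neutrophil, monocyte and plasma cell transcripts were called lower at the higher dose, and no call between the doses held with an estimated correlation (adjusted p = 0.599 to 0.672). Ribosomal protein transcripts were called higher, a direction that normexp turned to -0.16 and that quantile normalization left at 0.02 with camera's direction turned. Of 78 ribosomal protein genes 74 were higher (relative median 0.33), with Rpl37a at 1.02 ± 0.26, Rplp2 at 0.90 ± 0.23 and Rpl28 at 0.77 ± 0.21. Mature neutrophil genes were lower for 18 of 20 (median -0.77). Mmp8 lay at -1.60 ± 0.72, Trem1 at -1.06 ± 0.50, and Mmp25 at 0.73 ± 0.31. Of the granule and precursor genes 8 of 13 were lower (median -1.14), with Cebpe at -1.05 ± 0.36, Chi3l1 at -1.13 ± 0.48, and Ms4a3 at 0.92 ± 0.42. Monocyte genes were lower for 13 of 18 (median -0.78), with Klf4 at -1.19 ± 0.33 and Ccr2 at -0.82 ± 0.34, while Cx3cr1, whose probe imperfectly matches a brighter one, lay at 1.49 ± 0.52. Plasma cell genes were lower for 7 of 8 (median -0.64). Xbp1 lay at -0.78 ± 0.32, Sdc1 at -1.38 ± 0.73 and Prdm1 at -0.52 ± 0.32. Inflammatory genes were lower for 17 of 24 (median -0.67), with Myd88 at -0.70 ± 0.32, Tnfsf14 at -0.91 ± 0.41, and Osm at 0.84 ± 0.36. No call was left for neutrophils without 2 ml/kg array 4 (median -0.44, adjusted p = 0.0683), neutrophil granules without 0.5 ml/kg array 1 or 2 or 2 ml/kg array 3 or 4 (-1.01 to -0.25, 0.0801 to 0.151) and monocytes without 0.5 ml/kg array 2 or 2 ml/kg array 4 (-0.57 to -0.56, 0.0639 to 0.11). Calls ended for plasma cells without 0.5 ml/kg array 1 (-0.55, 0.0801) and inflammatory genes without 2 ml/kg array 4 (-0.46, 0.0585). Log2 changes were over 1.5 times smaller without 0.5 ml/kg array 2 for Osm (0.54), without 0.5 ml/kg array 3 for Ccr2 (-0.47) and without 2 ml/kg array 4 for Chi3l1 (-0.72), Tnfsf14 (-0.58) and Trem1 (-0.66).

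The other lists called lower at 2 against 0.5 ml/kg covered adhesion, metabolism and protein turnover. Adhesion and chemokine receptor genes were lower for 21 of 31 (relative median -0.48), with the integrin genes Itgal at -0.98 ± 0.29 and Itgb2 at -0.71 ± 0.28. Glucocorticoid-induced genes were lower for 12 of 19 (median -0.57), with Irs2 at -0.93 ± 0.35, Cebpd at -0.86 ± 0.44, and Cxcr4 at 0.47 ± 0.21. Glycolysis genes were lower for 20 of 31 (median -0.39). Ndrg1 lay at -1.33 ± 0.36, Bnip3 at least 2.37-fold lower, and Gapdh at 0.74 ± 0.30. Oxidative phosphorylation genes, 30 of 57 lower, had a median of -0.22, with Atp5f1c at -0.86 ± 0.24, Ndufs1 at -0.70 ± 0.21, and Uqcrq, whose probe imperfectly matches a brighter one, at 0.94 ± 0.34. Fatty acid oxidation genes were lower for 15 of 24 (median -0.46), with Etfdh at -0.85 ± 0.30, Cpt2 at -0.72 ± 0.27 and Eci1 at -0.71 ± 0.30. The proteasome list had 29 of 40 genes lower (median -0.35), with Psma1 at -0.85 ± 0.25, and with the chaperone genes Pdia6 at -0.92 ± 0.35 and Calr at 0.86 ± 0.34. Calls ended for glucocorticoid-induced genes without 0.5 ml/kg array 2 or 3 or 2 ml/kg array 1, 3 or 4 (median -0.57 to -0.28, adjusted p = 0.0529 to 0.0994), glycolysis without 0.5 ml/kg array 2 or 3 or 2 ml/kg array 3 or 4 (-0.36 to -0.25, 0.0529 to 0.11) and oxidative phosphorylation without 0.5 ml/kg array 1 or 2 ml/kg array 3 or 4 (-0.23 to -0.12, 0.0615 to 0.188). The call was lost for fatty acid oxidation without 2 ml/kg array 4 (-0.42, 0.054). Changes shrank by over 1.5 times without 2 ml/kg array 1 for Etfdh (-0.53), Gapdh (0.43) and Irs2 (-0.59) and without 2 ml/kg array 4 for Cebpd (-0.46).

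Between the doses limma called 0 genes (smallest adjusted p = 0.0541), with 4056 at unadjusted p below 0.05. Pik3c2b at 1.28 ± 0.24, Srp72 at 0.98 ± 0.18 and Dcaf6 at 1.497 ± 0.28 had the smallest p values on the higher side. On the lower side these were Trappc8 at -1.43 ± 0.25, Slc66a3 at -1.76 ± 0.32 and Fam118b at least 2.1-fold lower, and for all 6 the adjusted p was 0.0541. The further probes of Srp72 stood at -0.62 and -0.16. Camera called 12 lists at adjusted p = 2.34e-05 to 0.041, 1 higher and 11 lower. Adjusted over the list alone, 16 ribosomal protein genes passed as higher and 1 monocyte and 1 glycolysis gene as lower, with 0 in the other 9 lists and 0 over all genes tested in every list. The median of all genes was 0.18. At 2 ml/kg spots were above background on part of the arrays for Trappc8 (1), Slc66a3 (3), Fam118b (0), Mmp25 (3), Sdc1 (1), Prdm1 (2), Tnfsf14 (2) and Irs2 (2). The same held for Bnip3 (0), Etfdh (1) and Cpt2 (2).

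Fitted on the 8 STW5 arrays alone, 0 genes and 13 lists passed. Without array 1 or 4 of 0.5 ml/kg or array 3 of 2 ml/kg 227, 144 and 806 genes passed. Of the 12 lists 4 passed without STW5 2 ml/kg array 4. With the arrays' signal level as a covariate 2 of the 12 passed, granule genes and oxidative phosphorylation, and 3 others, erythroid genes as lower, interferon-stimulated genes as higher and cell cycle genes as lower. With the neutrophil list score as a covariate 1 of the 12 passed, with 3 in all. With spike-in scaling the median of all genes was -1.09, 7769 genes passed, all lower, and the named genes given here as higher turned lower except Pik3c2b, Dcaf6 and Cx3cr1. With normexp the median of all genes was 0.32, 3760 genes passed, 3413 higher and 347 lower, and Trappc8, Fam118b, Sdc1, Prdm1, Irs2, Bnip3, Etfdh and Cpt2 turned higher.

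**Figure D4:**
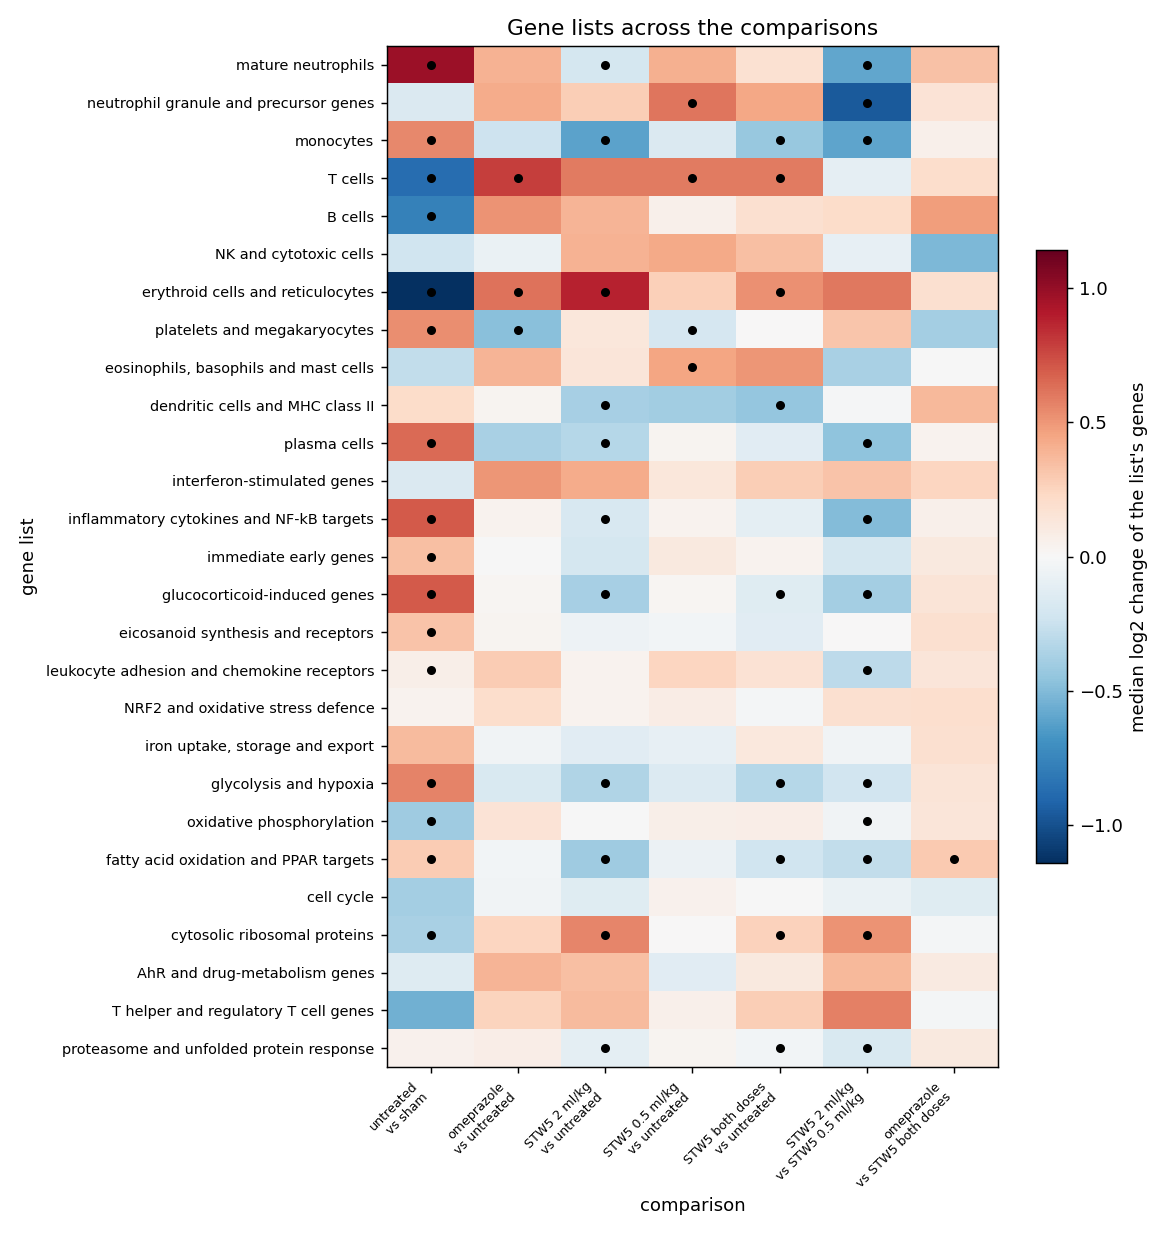
Median log2 change of the genes of each of 27 lists (y axis) in each of 7 comparisons (x axis), as colour from blue (lower) to red (higher), without subtracting the median of all genes. Dots mark lists past the threshold by camera with a preset correlation.

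Omeprazole was also compared with the mean of both STW5 doses, given to different rats and measured on different slides. By limma 741 genes differed, 32 higher and 709 lower with omeprazole, of which 156 had a gene symbol. Hist1h2bq lay at -5.17 ± 0.39 (adjusted p = 2.18e-08), with its further probe at -1.19, Txnip at -4.17 ± 0.38 (1.75e-07) and Prss3 was at least 10.5-fold lower (0.000483). On the higher side stood Batf3, a transcription factor gene of dendritic cells, at 1.43 ± 0.31 (0.00545), Phemx at 1.02 ± 0.24 (0.0113) and Hnrnpa2b1 at 1.01 ± 0.24 (0.013). In these 6 genes all 4 omeprazole arrays lay on one side of all 8 STW5 arrays. Fatty acid oxidation genes were called higher relative to all genes, 21 of 24 being higher (relative median 0.30), with Cpt2 at 0.57 ± 0.24, Decr1 at 0.46 ± 0.20 and Acadvl at 0.43 ± 0.19. Camera called this 1 list at adjusted p = 0.0168, and the call did not hold (adjusted p = 0.936 with an estimated correlation), with 0 members passing adjusted over the list alone and 0 over all genes tested.

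Of the 890 probes with an imperfect match 343 (38.5%) were called lower with omeprazole than with STW5, against 406 (2.48%) of the 16346 without, and 325 genes passed among probes without a match, 21 higher and 304 lower. Further probes, present for 32 of the 741 genes, had a median change of 0.04 where the called probes had -1.18. Spots were above background on part of the arrays for Batf3 (3 omeprazole, 2 STW5), Phemx (6 STW5), Txnip (1 omeprazole), Prss3 (0 omeprazole, 7 STW5) and Cpt2 (6 STW5). With spike-in scaling the median of all genes was 0.46 and 361 genes passed, 40 higher and 321 lower. Calls ended without omeprazole array 1 for Hnrnpa2b1 (adjusted p = 0.0534) and without omeprazole array 3 or 4 for Phemx (0.0548 and 0.0609), while normexp, at 0.30 and 0.43, ended those of Batf3 and Phemx (0.675 and 0.106), spike-in scaling that of Phemx (0.0566) and only the arrays compared that of Hnrnpa2b1 (0.0503). Without omeprazole array 1 or 4 there were 6 and 5 lists.

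To see whether treated rats lay closer to sham, each treatment's change from untreated rats was set against the change of untreated from sham rats across 15260 genes, which are not independent replicates. Pearson r was -0.555 for omeprazole, -0.685 for STW5 2 ml/kg and -0.569 for STW5 0.5 ml/kg. The untreated arrays enter both changes with opposite sign, which gives a negative r with no effect: in 100 simulations of unchanged groups r averaged -0.483 and ranged from -0.852 to 0.228. The covariance was -0.243, -0.276 and -0.159, where the spread of the untreated arrays alone gives -0.182 and the simulated groups averaged -0.0861. The differences from -0.182 were -0.061, -0.094 and 0.023. With the untreated arrays split, 2 for each change, the mean r over 6 splits was -0.142 (-0.412 to 0.136), -0.203 (-0.441 to 0.0091) and -0.0058 (-0.415 to 0.374). Without STW5 0.5 ml/kg array 1 the r of that dose was -0.367, and with the doses exchanged the values of both doses change places.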

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

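The tests of a local slide defect, of further probes, of array quality and of lymphocyte lists, the shuffling of signal values, and the alternatives with the signal level as a covariate or without an imperfect match, were chosen only after the result was seen.

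Probes lower on the omeprazole arrays may partly reflect how probes bound RNA of other genes on that slide, and 3 explanations were tested. Probes with an imperfect match to a brighter probe of another gene were called lower 16.47 times as often as others. For these this goes with less signal from mismatched binding on the omeprazole slide. A local slide defect is argued against, since the highest share of called spots in any band of rows or columns was 1.34 times that of the whole array. In the 25 called genes with a further probe, these probes had 0.085 times the change of the called ones (95% bootstrap interval -0.016 to 0.285). Called probes were chosen for their change and brightness, which alone can lower this ratio. Lower transcripts thus stay open, as for the 559 called genes without one. As omeprazole had its own slide, drug and slide cannot be told apart for the 242 called genes without an imperfect match either.

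Between the STW5 groups 12 gene lists passed with a preset correlation, none held with an estimated one (adjusted p = 0.599 to 0.672) or by fry, and 9 of 35 splits gave at least as many. They could go with the signal level of the arrays, which was lower at 2 ml/kg (71.3 to 163) than at 0.5 ml/kg (152 to 308). With log2 of the 75th percentile as a covariate 2 of the 12 still passed, which met the at most 2 set beforehand for this explanation, and 3 lists outside the 12 passed. Signal values shuffled within the groups left as few of the 12 in 17 of 100 draws (median 7), so the test does not decide, and signal level and dose cannot be told apart, because the ranges hardly overlap. Relative to the median of all genes, ribosomal protein genes went from 0.33 (0.46) to 0.08 (0.49), a smaller median at a like spread, and neutrophil genes from -0.77 (0.40) to -0.34 (0.94), a smaller median with a wider spread. The share of erythroid RNA as the whole cause is argued against, since 10 of the 12 lists passed with the erythroid list score as a covariate, and a biological difference between the doses stays open.

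Untreated array 2 stood apart, with 15 of 27 list scores outside the range of the other 19 arrays, 5 below and 10 above. Poor quality of the array is argued against, since 0 of its 5 quality values lay outside the range of the others. Both lymphocyte lists, 2 of 2, were below every other array, at -2.53 for T cells and -2.16 for B cells, and a candidate explanation is fewer lymphocytes in that blood sample, a hypothesis from the values that set the array apart. The lists of NK cells, dendritic cells and interferon-stimulated genes were also below every other array. Whether this came from the disease, the operation or the blood draw was not tested.

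Untreated array 1 lay with sham (mean r 0.984, and 0.92 to other untreated arrays). Without it the genes passing went from 1 to 1762 against sham, from 637 to 1142 with omeprazole, and from 0 to 3012 at 2 ml/kg and 161 for both doses. Whether its label is right, that rat had no esophagitis, or its signal level (75th percentile 124, the lowest of its group) plays a part was not tested and stays open.

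Other splits of the same arrays into groups of the same sizes were tested alike. For genes of omeprazole against untreated rats 1 of 35 splits, the real one, gave 637 (highest other 98). This is the least 35 splits can give, unadjusted over these tests, and argues against chance without excluding it. For omeprazole against both STW5 doses 2 of 100 gave at least the 741, but the highest other gave 2473, so chance is not excluded. Both comparisons follow the slides, so slide is not excluded. Nor is chance excluded for the 1 gene of untreated against sham rats, where 4 of 35 gave at least 1 (highest other 2069), or for any lists. At least as many lists came from 10 of 35 splits for untreated against sham rats (16 lists, highest other 19) and from 35 of 35 for omeprazole against untreated rats (3 lists, highest other 20). For STW5 2 ml/kg they came from 28 of 35 (11 lists, highest other 21), for 0.5 ml/kg from 32 of 35 (4 lists, highest other 22) and for both doses from 72 of 100 (9 lists, highest other 21). Between the doses it was 9 of 35 (12 lists, highest other 20), and for omeprazole against both doses 100 of 100 (1 list, highest other 19). Where the real groups gave 0 genes every split gives at least as many, 35 of 35 for each STW5 dose and between the doses and 100 of 100 for both doses, which tests nothing. The highest other splits there gave 4174 genes for 2 ml/kg, 2469 for 0.5 ml/kg, 4625 for both doses and 0 between the doses. Splits that call such numbers where the real groups call 0 genes, and the 2069 where they call 1, point to a structure of the samples other than these groups.

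Of 556 groups of 4 values, 20 held a value far from the other 3 of its group, where chance flags about 1 in 20 groups, and no explanation was tested for these. The scores of inflammatory cytokines and NF-kB targets on sham array 4 (-0.28, others -0.44 to -0.42), fatty acid oxidation and PPAR targets on untreated array 2 (0.70, others -0.18 to -0.037), glycolysis and hypoxia on STW5 2 ml/kg array 1 (0.16, others -0.21 to -0.14), T helper and regulatory T cell genes on STW5 2 ml/kg array 3 (0.056, others 0.37 to 0.38) and neutrophil granule and precursor genes on omeprazole array 3 (-0.28, others 0.36 to 0.40) stood apart. On omeprazole array 1, 43.1% of probes were well above background, where the other 3 had 51.4% to 52.7%. The levels of genes, as log2 over the array's 75th percentile, stood apart on 1 array each. Cd2 lay at -0.21 on STW5 0.5 ml/kg array 2 (others -0.52 to -0.47), Cpt2 at -2.21 on untreated array 1 (others -1.30 to -1.17), Decr1 at 0.065 on omeprazole array 3 (others 0.76 to 0.84), Eci1 at -1.36 on STW5 0.5 ml/kg array 4 (others -0.91 to -0.87) and Errfi1 at 0.47 on untreated array 2 (others -1.84 to -1.67). Fam118b lay at -3.64 on STW5 2 ml/kg array 3 (others -4.50 to -4.39), Fkbp5 at 0.84 on sham array 2 (others 0.19 to 0.22), Itgam at 0.60 on sham array 4 (others 1.11 to 1.17), Junb at 1.94 on sham array 1 (others 2.27 to 2.34) and Klf9 at 1.52 on untreated array 2 (others -0.26 to 0.042). Mapk8ip3 lay at -3.47 on omeprazole array 1 (others -2.60 to -2.56), Pfkfb3 at -1.93 on STW5 2 ml/kg array 3 (others -0.97 to -0.82), Prss3 at -2.84 on STW5 2 ml/kg array 4 (others 0.48 to 1.05) and RT1-DMa at 2.38 on STW5 2 ml/kg array 3 (others 1.24 to 1.40). 

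Treated groups were also compared directly. For omeprazole against both STW5 doses 741 genes and 1 list passed, in different rats on different slides, so drug and slide cannot be told apart for these. Neither this list nor the 12 between the STW5 doses held with an estimated correlation, and chance was not excluded for them.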

How the results depend on the processing

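The signal covariate, the restriction to probes without an imperfect match, the omission of 3 arrays and the gene-by-gene fit of array weights were chosen only after the result was seen. The 3 arrays were untreated array 2, for its list scores, and STW5 2 ml/kg arrays 1 and 2, for the lowest signal. Of 3017 values of the 217 named results under alternatives other than leaving out an array, 2716 kept direction and side of the threshold, 45 lost and 170 gained the threshold and 86 changed sign. Of 1904 values without 1 array, 1716 kept both, 44 lost and 144 gained the threshold and 0 changed sign. No named result past the threshold changed sign under any alternative run. In simulations of independent genes with equal group spread, unlike here, 32 to 46 of 50 changed 4-fold passed, and 4 to 19 changed 2-fold. The cause was not tested for any change below unless one is given.

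With spike-in scaling, which moves all genes of an array alike, these genes changed sign, to these log2 changes. In 2 ml/kg against untreated Alas2 -0.051, Cxcr4 -0.33, Pfkfb3 -0.17, Rpl37a -0.23, Rpsa -0.21, Rpl12 -0.21, Psmd4 -0.040. In both doses against untreated Rps10 -0.022. In 2 against 0.5 ml/kg Srp72 -0.29, Mmp25 -0.54, Ms4a3 -0.35, Osm -0.43, Cxcr4 -0.79, Gapdh -0.53, Uqcrq -0.32, Rpl37a -0.24, Rplp2 -0.36, Rpl28 -0.49, Calr -0.41. The median of all genes moved with it, to -0.87 for 2 ml/kg against untreated rats and -1.09 between the doses. With normexp the changed values were these. In untreated against sham Clock -0.14, Prdm1 -0.25, Hk2 -0.048. In 2 ml/kg against untreated Batf3 0.24, Fkbp11 0.20, Bnip3 0.020, Etfdh 0.22. In both doses against untreated Hif1a 0.042. In 2 against 0.5 ml/kg Trappc8 0.14, Fam118b 0.31, Sdc1 0.14, Prdm1 0.54, Irs2 0.16, Bnip3 0.12, Etfdh 0.28, Cpt2 0.17. With the deposited value table, whose STW5 columns follow the arrays of the other dose, which by construction exchanges the doses, they were these. In 2 ml/kg against untreated Trem1 0.089, Klf4 0.17, Alas2 -0.050, Xbp1 0.039, Bnip3 0.086, Etfdh 0.20, Rpl37a -0.18. In 0.5 ml/kg against untreated Camp -0.18, Mcpt8l2 -0.063, Mcpt8 -0.040. In 2 against 0.5 ml/kg Pik3c2b -1.13, Srp72 -0.83, Dcaf6 -1.35, Trappc8 1.51, Slc66a3 1.92, Fam118b 1.85, Mmp25 -0.58, Mmp8 1.75, Trem1 1.21, Cebpe 1.21, Chi3l1 1.28, Ms4a3 -0.77, Klf4 1.34, Cx3cr1 -1.34, Ccr2 0.97, Xbp1 0.93, Sdc1 1.53, Prdm1 0.67, Osm -0.69, Myd88 0.85, Tnfsf14 1.06, Irs2 1.07, Cxcr4 -0.32, Cebpd 1.01, Itgal 1.13, Itgb2 0.86, Ndrg1 1.48, Bnip3 1.93, Gapdh -0.59, Atp5f1c 1.01, Ndufs1 0.85, Uqcrq -0.79, Etfdh 1.00, Cpt2 0.78, Eci1 0.86, Rpl37a -0.87, Rplp2 -0.75, Rpl28 -0.62, Psma1 1.00, Pdia6 1.07, Calr -0.71.

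Counts of genes moved as follows. For untreated against sham rats the 1 gene became 0 with quantile normalization, spike-in scaling, normexp, no filter, only the arrays compared, eBayes with trend and robust, the replicate block, either list score or the signal level as a covariate, and without the 3 arrays, 556 with array weights (363 higher, 193 lower) and 3 with every probe on its own. The 637 genes of omeprazole against untreated rats became 403 with spike-in scaling, 382 with only the arrays compared, 1797 with array weights, 1249 with the erythroid covariate, 1189 with the signal covariate and 259 among probes without a match, all of these 259 among the 637. The 0 genes of 2 ml/kg became 2 with the array median, 3672 with spike-in scaling and 37 with the replicate block, and those of 0.5 ml/kg 2 with the deposited table and 1 with the signal covariate. Between the doses the 0 genes became 79 with the array median (55 higher, 24 lower), 79 with the deposited table (24 higher, 55 lower), 7769 with spike-in scaling (0 higher), 3760 with normexp (3413 higher), 5394 with no filter (5134 higher), 118 with the filter of 10 arrays (95 higher), 529 with the replicate block (446 higher), 3 with every probe on its own and 1205 with the erythroid covariate (981 higher). The 741 genes of omeprazole against both doses became 361 with spike-in scaling, 3511 with array weights, 1583 with the erythroid covariate, 1363 with the signal covariate and 325 among probes without a match, all of them among the 741.

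Counts of lists became 0 in all 7 comparisons with an estimated correlation and with fry. The 16 lists of untreated against sham became 5 with the neutrophil covariate (4 among the 16). The 3 of omeprazole against untreated became 6 with no filter, 1 with array weights and 6 without the 3 arrays. The 11 of 2 ml/kg became 5 with the deposited table, 18 with no filter and 4 with the doses exchanged. The 4 of 0.5 ml/kg became 9 with normexp, 11 with the deposited table, 9 with no filter, 8 with array weights, 7 with the neutrophil covariate, 10 without the 3 arrays and 11 with the doses exchanged. The 9 of both doses became 15 with no filter. The 12 between the doses became 5 with spike-in scaling (3 among the 12), 20 with no filter (11), 3 with the neutrophil covariate (1) and 5 with the signal covariate (2). The 1 of omeprazole against both doses became 2 with quantile normalization, spike-in scaling, normexp, the replicate block or the erythroid covariate, 6 with no filter, only the arrays compared or array weights, 4 with the neutrophil covariate, 5 without the 3 arrays and 3 among probes without a match. The correlation across genes with the change of untreated from sham rats became -0.629 for omeprazole with no filter. For 2 ml/kg it became -0.774 with normexp, -0.749 with no filter and -0.569 with the deposited table or the doses exchanged, and for 0.5 ml/kg -0.449, -0.394 and -0.685.

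Leaving out 1 array at a time gave these lowest and highest counts of genes and of lists: untreated against sham 0 to 1762 and 12 to 18, omeprazole against untreated 468 to 1142 and 2 to 6, STW5 2 ml/kg against untreated 0 to 3012 and 8 to 17, STW5 0.5 ml/kg against untreated 0 to 5 and 4 to 11, both doses against untreated 0 to 161 and 6 to 14, 2 against 0.5 ml/kg 0 to 806 and 6 to 14, and omeprazole against both doses 542 to 858 and 1 to 6. The correlations ranged from -0.719 to -0.453 for omeprazole, -0.816 to -0.637 for 2 ml/kg, -0.787 to -0.367 for 0.5 ml/kg.

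The replicate numbers were not taken to pair the rats. Arrays of the same number in different groups correlated, after group means were removed, at -0.437 to 0.588 (median 0.092), 19 of 40 pairs above 0.1, against a median of -0.038 and 37 of 120 pairs for other numbers. The number is also the array's column on its slide, and 5 of 20 arrays matched best with their own number.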

Other observations

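Of the 27 gene lists, 7 passed by camera in none of the 7 comparisons, and fry gave 0 as well. Cell cycle genes came nearest, with 28 of 31 lower in untreated than in sham rats and a median log2 change of -0.20 relative to all genes, as for all medians here (adjusted p = 0.0796). Genes of T helper and regulatory T cells were higher for 16 of 19 members at STW5 2 ml/kg than in untreated rats, with a median of 0.22 (adjusted p = 0.0876), and NK and cytotoxic genes for 16 of 21 at 0.5 ml/kg, with a median of 0.41 (adjusted p = 0.0883). Genes of iron uptake, storage and export were higher for 11 of 17 members in untreated than in sham rats, with a median of 0.55 (adjusted p = 0.0905). Interferon-stimulated genes were higher for 30 of 43 members with omeprazole than in untreated rats, with a median of 0.40 (adjusted p = 0.117). Against both STW5 doses, omeprazole gave a median of 0.20 for NRF2 and oxidative stress genes, 21 of 29 being higher (adjusted p = 0.126), and of 0.10 for AhR and drug-metabolism genes, 7 of 11 being higher (adjusted p = 0.411). Each is the list's smallest adjusted p over the 7 comparisons.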
